A study of Homo sapiens with 46 samples.

How the data were processed

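Gene expression was measured on the A and B arrays of the Affymetrix human U133 set (array types A and B) in monocytes of 8 patients with systemic lupus erythematosus, chosen per the labels from 19 screened patients by whether their monocytes made CD4 T cells proliferate in a mixed lymphocyte reaction. The 4 donors whose monocytes did so are called MLR-positive and the 4 whose monocytes did not are called MLR-negative. Per the labels, 20000 monocytes per well were taken at 0 h, after 6 h of culture alone, or after 6 h with 100000 CD4 T cells, and the harvested cells were depleted of T cells with CD3 beads before RNA extraction. The kit used to extract the RNA depended on the number of cells recovered and is not given per sample. Labelling used a kit with amplification in 2 cycles. 1 MLR-positive donor has no 0 h sample, so 23 RNA samples on 46 arrays fall into 6 groups.

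The deposited values are intensity values on a linear scale. On every array the mean over probe sets, without the lowest and highest 2%, lay between 500.2 and 500.3, so the authors had scaled each array to a target of 500. The software behind the intensity values is not given in the sources used here. Array A holds 22283 probe sets and array B 22645. Array medians ran from 106.2 to 189 on array A and from 193 to 254.1 on array B, a spread of 0.83 and 0.40 on the log2 scale. That exceeded the bound of 0.2 set beforehand, so the 23 arrays of each type were quantile normalised. Values under 16 were set to 16 and the log2 was taken. Between 4.77% and 16.9% of the probe sets of an array A, and between 2.06% and 5.28% of an array B, were below 16 as deposited. The number of arrays limits the precision.

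Gene symbols came from the platform tables that pair probe sets with Entrez genes, updated through a RefSeq gene table (assembly GRCh38.p14, used for names only). On array A 19071 probe sets matched 1 gene, 1043 matched several and 2169 matched none, and on array B 15432, 554 and 6659 did. Control probe sets were left out, as were 52 probe sets of array A and 32 of array B for genes linked to the sex chromosomes. Probe sets whose mean over the 23 samples lay under the 40th percentile of their array type were left out as dim. Each gene was represented by its brightest probe set, from array A where both types measured it, which left 12317 genes, 7972 on array A and 4345 on array B.

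Each gene was tested with limma 3.58.1 in R 4.3.3 (linear model and moderated statistic), each array type on its own, with Benjamini-Hochberg adjustment over the genes of both types and a threshold of 0.05. Changes within donors were fitted over all 23 samples with the donor as a fixed block, which leaves 11 residual degrees of freedom. The donor pairing comes from the labels. Values of the same donor, taken as deviations from their group means, had a median correlation across genes of 0.015 over 22 pairs, against -0.0052 over 154 pairs of different donors. Contrasts between classes used only the samples of the condition compared, so that donors were the replicates. 11 comparisons were made: the change with culture and the change with CD4 T cells, each as the mean of both classes, within each class and as the difference between classes, and the difference between classes in each of 3 conditions. All tests were two-sided. For changes within donors, limma's p-values rest on the spread left after the donor block, pooled over all 6 groups. For contrasts between classes they rest on the spread between the donors in the condition compared.

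26 gene lists, covering interferon response, antigen presentation, inflammation, monocyte and macrophage genes, markers of other blood cells, stress and metabolism, were tested with camera at a preset inter-gene correlation of 0.01 on the genes of array A, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. Camera compares a list's genes with the other genes, so its p-values also rest on the spread across genes. Where a list's count is given as adjusted over the list alone, the adjustment ran over that list's measured genes. List levels between classes were compared by an exact permutation test of the mean log2 value per sample. The lists, the comparisons, the tests and the rule for named genes were chosen before the data were examined. That rule took, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold that moved the same way in every donor, or the 10 smallest p-values where fewer than 6 such genes existed. It added a panel of 25 genes and up to 4 members of each list with the smallest p. Of that panel CCL22, FSCN1, IL10 and FCGR3A were not among the tested genes. Genes whose level marks an inherited genotype were never named.

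The gene test was tried on simulated data of the same design with 12317 genes, 200 of them changed by 1, 2 or 3 on the log2 scale. For the change with CD4 T cells it recovered 41.8%, 85.1% and 98.5% at these sizes as the mean of both classes with 11 false calls, 16.4%, 68.7% and 83.3% in MLR-negative donors with 7, and 29.9%, 68.7% and 86.4% in MLR-positive donors with 8. The difference of that change between classes gave 4.48%, 50.7% and 77.3% with 6. For culture it recovered 38.8%, 85.1% and 95.5% as the mean of both classes with 4, 28.4%, 61.2% and 86.4% in MLR-negative donors with 7, 11.9%, 59.7% and 84.8% in MLR-positive donors with 5, and 0%, 35.8% and 63.6% for the difference between classes with 3. Between classes it recovered 4.48%, 53.7% and 71.2% at 0 h with 6 false calls, 14.9%, 55.2% and 80.3% at 6 h alone with 8, and 19.4%, 61.2% and 80.3% with CD4 T cells with 3. The simulated values held the spread left after the donor block and no differences between donors. Recovery between classes is therefore too high for genes whose level varies between donors. For the change with CD4 T cells, camera on 7972 simulated genes called a list raised by 1 in 20 of 20 runs and made 0 calls when no list was changed. The simulated genes were drawn independently of each other, so these runs do not show how often camera calls a list of correlated genes by chance. In the data the estimated correlation of interferon-stimulated genes was 0.61 for that change.

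Alternatives changed 1 choice at a time, except that the trend and robust variances were set together and that, between classes, the donor as a random effect came with all 23 samples. They were no donor block, the donor as a random effect, the samples of the contrast alone, the deposited scaling, scaling to the 75th percentile, no filter or a filter at the 60th percentile, log2 of the value plus 16, every probe set on its own, array A alone, array weights, and a trend with robust variances. Each donor was also left out in turn. Leaving out samples that stood apart and a covariate for the ratio of 3' to 5' GAPDH signal were chosen after seeing the data. As a check on the pairing of array types, 100 shared probe sets were compared, and 22 of the 23 samples matched their own other array best.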

Results

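Expression was profiled in blood monocytes of 8 lupus patients, 4 MLR-negative and 4 MLR-positive, where the MLR is a mixed lymphocyte reaction in which monocytes are tested for making CD4 T cells divide. The samples comprised 4 MLR-negative and 3 MLR-positive at 0 h, 4 and 4 after 6 h of culture alone, and 4 and 4 after 6 h with CD4 T cells followed by T cell depletion. Each of the 23 RNA samples was hybridised to array types A and B, giving log2 intensity for 12317 genes. The labels give the purpose as finding transcripts that differ by the monocytes' capacity to induce the reaction.

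The first principal component, with 26.6% of the variance, separated the 0 h samples from the cultured ones, and the second, with 8.02%, separated culture with CD4 T cells from culture alone. 2 samples stood apart. The MLR-positive 6 h sample of donor 4 lay at -9.90 on the first component, against 25.01 to 42.57 for the other 7 samples cultured alone. The MLR-negative sample with CD4 T cells of donor 1 lay at -6.66, against 18.64 to 40.91 for the other 7 of that condition. The log2 ratio of 3' to 5' GAPDH signal, a sign of RNA quality, was 1.34 ± 0.28 (SD, n = 4) and 1.64 ± 0.23 (n = 3) at 0 h in MLR-negative and MLR-positive donors. It was 1.99 ± 0.42 and 2.12 ± 0.64 at 6 h alone, and 1.82 ± 0.33 and 1.46 ± 0.27 with CD4 T cells (n = 4 each). In the MLR-positive 6 h sample of donor 4 the mean level of interferon-stimulated genes was 11, against 9.29 to 9.45 in the other 3 MLR-positive samples at 6 h alone. At 0 h that list lay between 8.39 and 11.42, and at 10.41 in that donor.

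**Figure D1:**
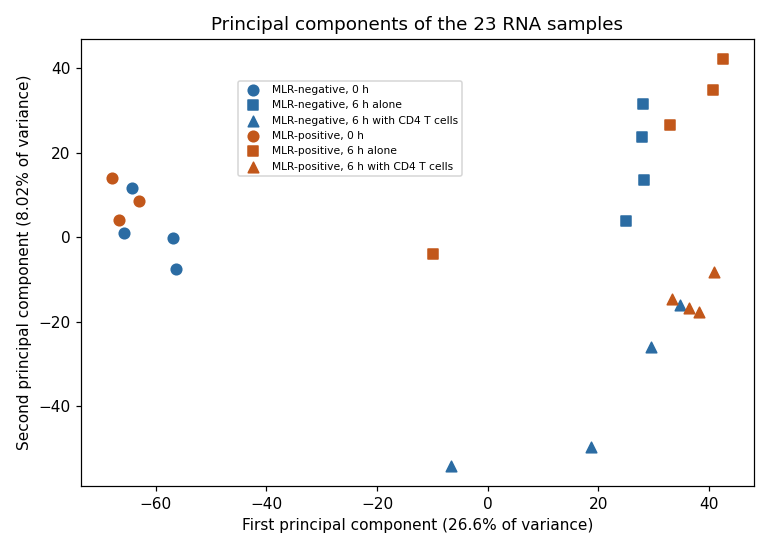
The 23 RNA samples on the first (26.6% of variance, x axis) and second (8.02%, y axis) principal components of log2 intensity, in component units, with a point per sample, colour for the donor class and shape for the condition. The MLR-positive 6 h sample of donor 4 lies at -9.90 and the MLR-negative CD4 sample of donor 1 at -6.66 on the x axis, between the 0 h samples and the other cultured ones.

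After 6 h of culture without T cells SLC7A11, the cystine transporter, rose by 8.77 ± 0.35 on the log2 scale (SE; higher in 7 of 7 donors; adjusted p = 2.3e-09). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 5.60 ± 0.29, and HMOX1, the heme-degrading oxygenase, by 4.34 ± 0.25. CD69, an early activation marker, fell by 4.25 ± 0.36, FOSB, a part of the AP-1 transcription factor, fell by 2.89 ± 0.20, and CX3CR1, the fractalkine receptor, fell by 3.33 ± 0.54, each in 7 of 7 donors. In all, 3536 of 12317 genes changed, 1569 higher and 1967 lower.

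The other large rises, also in 7 of 7 donors, were of SPINK1, a trypsin inhibitor, by 6.95 ± 0.52, the neutrophil chemokine CXCL5 by 6.71 ± 0.36 and the hepatocyte growth factor receptor MET by 6.47 ± 0.20. MET was at the floor of 16 in 6 of the 7 samples at 0 h, so the size of its rise depends on the floor. 3 other MET probe sets gave 1.76 ± 0.35, 0.27 ± 0.19 and -0.11 ± 0.59. The aldo-keto reductase AKR1C3 rose by 6.10 ± 0.33, the phosphodiesterase-binding protein PDE4DIP by 6.08 ± 0.46, the monocyte chemokine CCL2 by 6.05 ± 0.73, CT75 by 5.97 ± 0.49 and the fatty acid elongase ELOVL7 by 5.65 ± 0.45. Among the falls, the mitochondrial reductase MTARC1 fell by 4.57 ± 0.48, the ADP receptor P2RY13 fell by 3.87 ± 0.83 and the endosomal RNA sensor TLR8 fell by 3.55 ± 0.69. The nuclear receptor NR4A2 fell by 3.53 ± 0.21, the Golgi protein GOLM1 fell by 3.11 ± 0.53, the kinase anchor AKAP7 fell by 2.92 ± 0.35 and the tubulin TUBA1A fell by 2.80 ± 0.36. Adjusted p among these genes was at most 0.003 (P2RY13). P2RY13 was at the floor in 2 of the 4 MLR-positive samples at 6 h, and TLR8 in 2 samples of each class, so the sizes of their falls depend on the floor. A brighter TLR8 probe set of array B fell by 1.33 ± 0.30. In the panel, the inhibitory ligand CD274 rose by 2.04 ± 0.45 (7 of 7 donors, adjusted p = 0.0038), while the costimulatory ligand CD86 fell by 0.87 ± 0.26 (6 of 7, 0.021), CD83 fell by 0.54 ± 0.18 (6 of 7, 0.033), IL15 fell by 1.41 ± 0.34 (6 of 7, 0.0064) and the interferon-induced chemokine CXCL10 fell by 1.72 ± 0.46 (6 of 7, 0.012). Other probe sets gave smaller changes for CD274 (0.48 ± 0.28), CD86 (-0.20 ± 0.14), CT75 (1.54 ± 0.53), SLC7A11 (5.34 ± 0.23), CXCL5 (1.21 ± 0.56 and 1.65 ± 0.65), PDE4DIP (3.02 ± 0.40 and 3.04 ± 0.35) and AKAP7 (-0.65 ± 0.58 and -0.03 ± 0.41). The call on CXCL10 ended in 2 of 23 alternatives, that on CD83 in 12 and that on CD86 in 5, including a GAPDH ratio covariate for CD86 (-0.70, adjusted p = 0.13).

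**Figure D2:**
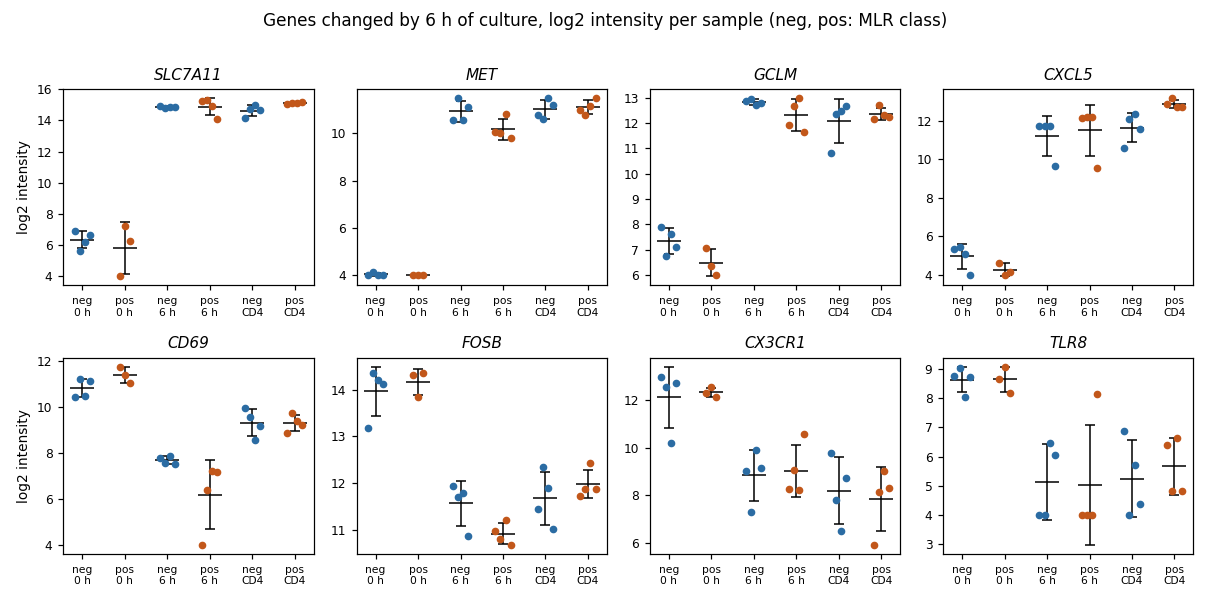
Log2 intensity (y axis) of 8 genes changed by 6 h of culture in the 6 groups (x axis; neg and pos are MLR-negative and MLR-positive), with a point per sample, and the mean and SD in black (n = 4, or 3 for MLR-positive at 0 h). SLC7A11 rose by 8.77 and CD69 fell by 4.25 as the mean of both classes; a value of 4 is the floor.

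Of 31 measured inflammatory cytokines and NF-kB targets, 13 rose and 4 fell in culture, 15 and 4 adjusted over the list alone. They included the chemokines CXCL3 (5.06 ± 0.29) and CXCL2 (2.64 ± 0.24) and the activin subunit INHBA (4.83 ± 0.34). The list was called higher by camera (adjusted p = 0.0016), with adjusted p = 0.54 with an estimated correlation. Of 21 macrophage and scavenger genes, 8 rose and 1 fell, the same 8 and 1 adjusted over the list alone, among them GPNMB, a lysosomal glycoprotein (5.17 ± 0.25), the lipid droplet protein PLIN2 (3.12 ± 0.16) and the fatty acid binding protein FABP5 (2.64 ± 0.22). That list had a camera adjusted p of 0.0016, and adjusted p = 0.27 with an estimated correlation. Among 15 genes of MHC class II presentation, 3 rose and 4 fell, the same adjusted over the list alone. The proteases CTSL (4.11 ± 0.26), LGMN (4.65 ± 0.35) and CTSB (1.57 ± 0.18) rose and CTSS fell by 1.49 ± 0.20. The list's median was -0.46 and its mean 0.20, and camera did not call it (adjusted p = 0.88). Of 22 costimulatory and inhibitory ligands, 6 rose and 6 fell, 7 and 7 adjusted over the list alone, with SLAMF7 at 4.71 ± 0.40 and TNFSF14 at 4.83 ± 0.53; their median was -0.14, their mean 0.31, and camera gave adjusted p = 0.92. HAVCR2, an inhibitory receptor of that list, rose by 2.69 ± 0.33.

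Of 39 interferon-stimulated genes, 16 fell in culture and 1 rose (18 and 1 adjusted over the list alone), among them EIF2AK2, the RNA-activated kinase (-2.36 ± 0.44), BST2 (-1.37 ± 0.25) and IFIT5 (-1.88 ± 0.43). Camera gave adjusted p = 0.0021, and adjusted p = 0.78 with an estimated correlation. The list's mean level rose in MLR-negative donor 3 (8.39 to 9.76) and in MLR-positive donor 4 (10.41 to 11), whose 6 h sample stood apart. It fell in the other donors with both samples. Of 26 genes induced by interferon gamma, 8 fell and 1 rose (11 and 1 adjusted over the list alone), with the immunoproteasome subunits PSMB9 at -1.80 ± 0.23 and PSMB8 at -1.51 ± 0.22 (camera adjusted p = 0.0018, and adjusted p = 0.54 with an estimated correlation). Of 28 genes of oxidative phosphorylation, 17 fell, also 17 adjusted over the list alone, such as the ATP synthase subunits ATP5F1C (-1.19 ± 0.14) and ATP5F1A (-1.24 ± 0.16) and the complex I subunit NDUFB5 (-1.08 ± 0.19). Camera gave adjusted p = 0.00071, and adjusted p = 0.29 with an estimated correlation. Of 22 classical monocyte genes, 11 fell and 2 rose (15 and 2 adjusted over the list alone), with MNDA at -2.12 ± 0.33, PLBD1 at -1.55 ± 0.24 and the cytochrome CYP1B1 at 2.55 ± 0.17 (camera adjusted p = 0.0016, and adjusted p = 0.29 with an estimated correlation). Of 17 genes induced by glucocorticoids, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with TSC22D3 at -1.65 ± 0.24, DUSP1 at -0.81 ± 0.14 and the rising THBS1 at 2.83 ± 0.55. Camera gave adjusted p = 0.017, and adjusted p = 0.54 with an estimated correlation; without MLR-negative donor 3 the camera value was 0.067 and without MLR-positive donor 1 it was 0.059. The 7 lists called here thus ended as calls with an estimated correlation, and over all 286 list tests camera made 40 calls, 3 with an estimated correlation.

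Among the lists camera did not call in culture, stress and immediate early genes went both ways, with 5 of 19 higher and 8 lower (7 and 8 adjusted over the list alone): FOS fell by 2.71 ± 0.24 and ZFP36 fell by 1.92 ± 0.21, while the chaperone HSPH1 rose by 2.95 ± 0.23. The list's median was 0.03 and its mean -0.37 (camera adjusted p = 0.65). Of 20 toll-like receptor and inflammasome genes, 3 rose and 8 fell (3 and 11 adjusted over the list alone), with the kinases IRAK1 at 2.11 ± 0.18 and IRAK2 at 2.82 ± 0.44, the adaptor PYCARD at -1.73 ± 0.24 and the sensor NLRP3 at -1.56 ± 0.25 (camera adjusted p = 0.21). Of 14 T cell markers, 4 rose, also 4 adjusted over the list alone: LAT by 2.55 ± 0.22, ZAP70 by 1.10 ± 0.26, CD3D by 1.10 ± 0.30 and TRAT1 by 0.88 ± 0.31 (camera adjusted p = 0.13). With fry, which asks only whether a list's genes move on balance 1 way, the list had adjusted p = 0.002. The calls on CD3D and TRAT1 ended in 4 of 22 and 12 of 21 alternatives. Platelet markers gave 0 of 11 changed genes in limma over all genes and 0 adjusted over the list alone (camera adjusted p = 0.88), and the unadjusted count over all genes was 4668. Their GNG11 was at 1.74 ± 0.82 (higher in 5 of 7 donors, adjusted p = 0.13).

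Camera also called none of the other lists in culture. Of 27 genes of mature migratory dendritic cells 7 rose and 5 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.52), among them IL7R (2.79 ± 0.32), the signalling adaptor TRAF1 (2.64 ± 0.33) and TBC1D4 (-1.71 ± 0.35). Of 17 CD16 monocyte genes, a list that holds HMOX1 and CX3CR1, 5 rose and 5 fell (5 and 8 adjusted over the list alone; median -0.31, mean 0.15; camera adjusted p = 0.88). Of 10 activated T cell cytokines and receptors 1 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.28, mean -0.24; 0.89). Of 9 plasmacytoid dendritic cell markers 3 rose and 1 fell, the same adjusted over the list alone (0.49), with the semaphorin receptor NRP1 at 3.05 ± 0.50. Single members rose among 9 B cell markers (CD22, 1.56 ± 0.36; 0.88), 6 red cell markers (HBB, 1.09 ± 0.23; 0.73) and 9 plasma cell and proliferation genes (PCNA, 2.51 ± 0.22; 0.78), each 1 also adjusted over the list alone. The medians of the B cell and plasma cell lists were -0.02 and -0.06, their means 0.10 and 0.26. Of 8 NK and cytotoxic markers 1 rose, GZMB (0.97 ± 0.34), and 0 did adjusted over the list alone (0.52); the GZMB call ended in 14 of 19 alternatives. Of 14 granulocyte markers 1 rose and 1 fell, also adjusted over the list alone (0.88), KCNJ15 (2.37 ± 0.45) and the peroxidase MPO (-1.53 ± 0.40). Of 15 cholesterol synthesis genes 3 rose and 1 fell, the same adjusted over the list alone (0.52), with SC5D at 1.39 ± 0.25. Of 23 genes of glycolysis and hypoxia 1 rose and 6 fell (2 and 6 adjusted over the list alone; 0.78), with LDHA at -0.83 ± 0.14 and the peptide hormone ADM at 1.40 ± 0.26. Of 21 apoptosis regulators 3 fell, also adjusted over the list alone (0.73), such as the survival factor MCL1 (-1.14 ± 0.24), and of 27 ribosomal proteins 2 fell and 0 did adjusted over the list alone (0.98).

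Other probe sets of some list members gave the opposite sign or a smaller change in culture. These were INHBA (-0.02 ± 0.59), PLIN2 (-0.06 ± 0.47), ATP5F1C (0.36 ± 0.31), TSC22D3 (0.83 ± 0.57), MCL1 (0.56 ± 0.61 and 0.04 ± 0.27) and NRP1 (-0.14 ± 0.42). On array B they were TNFSF14 (1.11 ± 0.23), SLAMF7 (2.34 ± 0.55), CXCL2 (0.13 ± 0.42), TRAF1 (0.80 ± 0.40), EIF2AK2 (-0.18 ± 0.42) and KCNJ15 (0.0047 ± 0.22). Others kept the sign, such as those of INHBA (4.30 ± 0.46), ATP5F1C (-1.10 ± 0.08), MCL1 (-1.52 ± 0.10) and NRP1 (1.62 ± 0.49). Of 92 other probe sets of 41 list members past the threshold 15 gave the opposite sign.

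**Figure D3:**
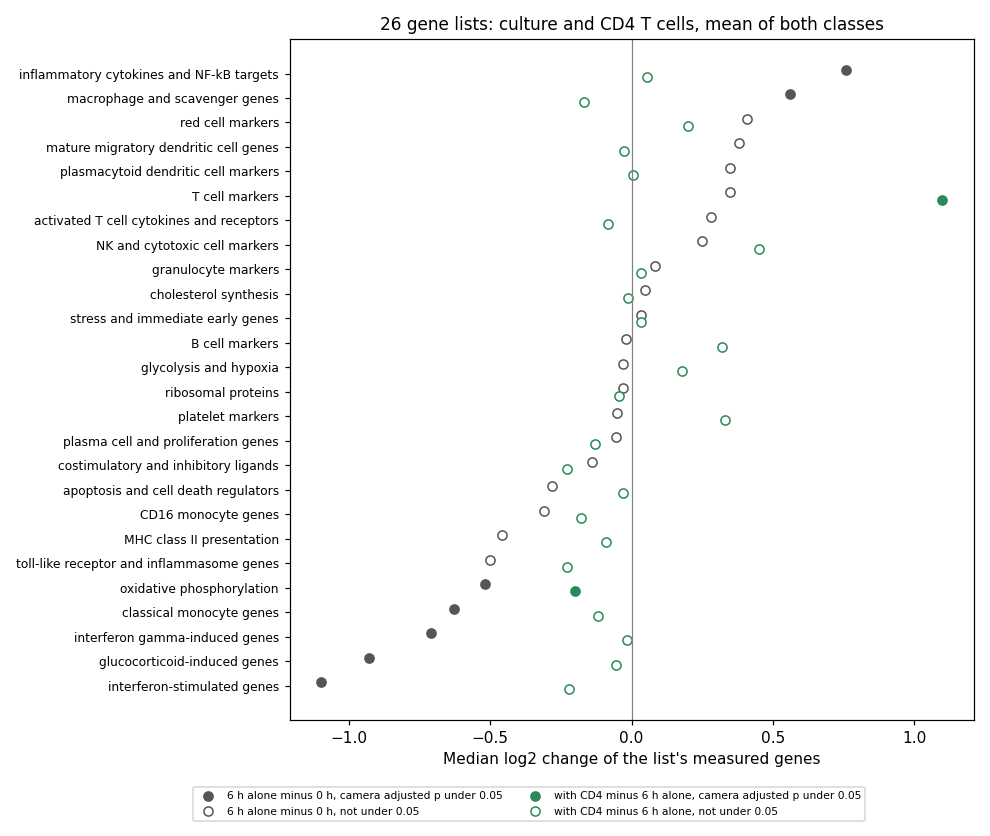
Median log2 change (x axis) of the measured genes of 26 gene lists (y axis) for 6 h alone minus 0 h (grey) and 6 h with CD4 T cells minus 6 h alone (green), mean of both classes, with filled points for lists camera called at the preset correlation. Interferon-stimulated genes lie at -1.1 in culture and T cell markers at 1.11 with CD4 T cells; the only filled point that stays a call with an estimated correlation is that of T cell markers.

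Within classes, culture changed 1961 genes in MLR-negative donors (941 higher, 1020 lower) and 1776 in MLR-positive donors (866 higher, 910 lower). 1122 genes were shared, and 1121 of them moved the same way. Independent calls would share 283. Both classes were tested with the same estimate of spread per gene, so their calls were not independent and that level is too low. Across genes, which are not independent replicates, the changes in the classes had a Pearson correlation of 0.70. limma found 0 genes whose culture response differed between classes, with 658 at an unadjusted p under 0.05 against 616 by chance. The smallest p was that of DHRS7C (difference 2.47 ± 0.50, adjusted p = 0.86). Camera called 4 lists in both classes: inflammatory cytokines and macrophage genes higher, and genes induced by interferon gamma and oxidative phosphorylation lower. It called 5 more in MLR-negative but not in MLR-positive donors, which by itself is no test of a difference between classes. Interferon-stimulated, classical monocyte, glucocorticoid-induced and toll-like receptor genes were lower. T cell markers were higher (median 0.70, adjusted p = 0.022, and 0.061 without MLR-negative donor 2), with a median of 0.11 in MLR-positive donors (adjusted p = 0.66). None of these calls held with an estimated correlation, where the smallest adjusted p was 0.25 and 0.15. For the list of classical monocyte genes the difference was a median of 0.26 (camera adjusted p = 0.044, and adjusted p = 0.44 with an estimated correlation). Stress and immediate early genes (-0.35, 0.0069) and toll-like receptor and inflammasome genes (0.35, 0.0065) both had adjusted p = 0.37 with an estimated correlation. Camera did not call the difference for interferon-stimulated genes (adjusted p = 0.084), genes induced by glucocorticoids (0.19) or T cell markers (0.19). With only the samples of the contrast the counts were 950 and 59. Without MLR-negative donor 1, 2 or 4 the MLR-negative count was 1305, 1002 or 1083, without MLR-positive donor 1 or 2 the MLR-positive count was 627 or 727, and without MLR-negative donor 2 the count of differing genes was 1.

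CD4 T cells in the culture went with higher KIT, MYB and GATA3, and with higher T cell markers, in both donor classes. KIT, the stem cell factor receptor, rose by 4.94 ± 0.40 on the log2 scale over 6 h alone (SE; higher in 8 of 8 donors; adjusted p = 2.2e-05). Its mean over all samples was only 6.57, so at 6 h alone it lay near the floor. The size of its rise may therefore depend on the floor, and was 4.39 to 5.22 over 22 alternatives. The transcription factors MYB and GATA3 rose by 4.53 ± 0.31 and 3.66 ± 0.24 (8 of 8 donors; adjusted p = 3.4e-06 each). GPX4, the lipid peroxidase, fell by 1.27 ± 0.18 (8 of 8 donors; adjusted p = 0.0038). Of 12317 genes, 306 changed, 207 higher and 99 lower.

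The other large rises, all in 8 of 8 donors, were of the nucleotide exporter ABCC4 (3.66 ± 0.40), the muscarinic receptor CHRM3 (3.29 ± 0.49), the protein kinase A subunit PRKACB (3.21 ± 0.50), TESPA1, which acts in T cell receptor signalling (3.07 ± 0.50), the nuclear receptor RORA (3.01 ± 0.43), NLRC3 (3.01 ± 0.43) and CNRIP1 (2.96 ± 0.41). Their adjusted p was at most 0.006 (TESPA1). ABCC4 was at the floor in 3 of the 4 MLR-positive samples at 6 h alone, so the size of its rise depends on the floor. Another ABCC4 probe set gave 0.56 ± 0.67. The falls, in 8 of 8 donors, were of SERPINA6, the corticosteroid carrier (-2.05 ± 0.39), TMEM37 (-1.79 ± 0.33), TRIM65 (-1.72 ± 0.34), the collagen COL22A1 (-1.66 ± 0.32), PRAMEF11 (-1.65 ± 0.30), PRX (-1.51 ± 0.29), UPK1B (-1.49 ± 0.36), the centromere protein CENPB (-1.34 ± 0.22) and EVA1B (-1.33 ± 0.29). Their adjusted p was at most 0.044 (UPK1B). Other probe sets of MYB (-0.56 ± 0.46), RORA (-0.18 ± 0.54), PRX (0.08 ± 0.23), COL22A1 (1.00 ± 0.56), EVA1B (0.01 ± 0.33) and TRIM65 (0.05 ± 0.12) gave the opposite sign. They were 6 of 23 other probe sets of the 13 largest and panel genes past the threshold that had any. The other 6 of RORA had its sign (3.56 ± 0.65, 2.95 ± 0.48, 1.90 ± 0.80, 1.87 ± 0.37, 0.44 ± 0.69 and 0.0022 ± 0.51), as had 1 each of EVA1B (-1.68 ± 0.27) and COL22A1 (-0.37 ± 0.84). Smaller changes came from other probe sets of GATA3 (2.70 ± 0.52 and 2.40 ± 0.37), PRKACB (2.17 ± 0.37 and 1.73 ± 0.42), TMEM37 (-1.24 ± 0.39) and UPK1B (-0.26 ± 0.58). The calls on KIT, MYB, GATA3, ABCC4, PRKACB, RORA, NLRC3, CNRIP1, TMEM37 and GPX4 held in each of the 21 to 23 alternatives that tested the gene with 1 probe set. The calls on UPK1B and EVA1B ended in 14 of 22 and 13 of 23, those on SERPINA6, COL22A1 and PRX in 6 each, that on TRIM65 in 5, that on PRAMEF11 in 2 and that on CENPB in 1. With no filter, which took dimmer probe sets of array A, CHRM3 was at 0.26 (adjusted p = 0.78) and TESPA1 at 1.21 (adjusted p = 0.22).

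**Figure D4:**
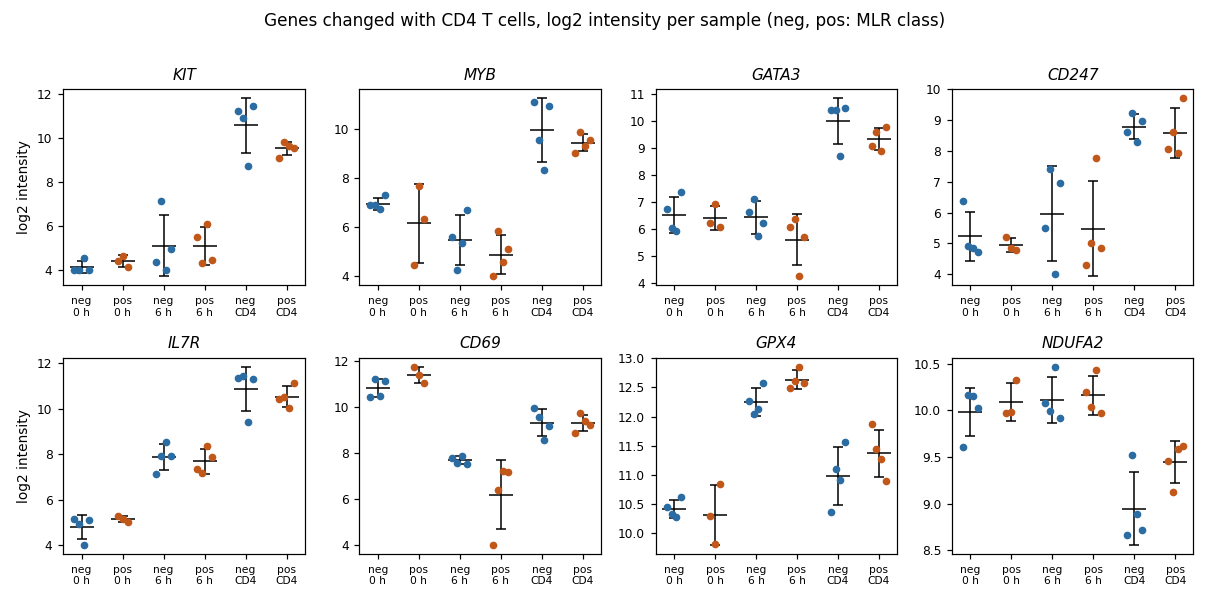
Log2 intensity (y axis) of 8 genes changed with CD4 T cells in the 6 groups (x axis; neg and pos are MLR-negative and MLR-positive, CD4 is 6 h with CD4 T cells), with a point per sample, and the mean and SD in black (n = 4, or 3 for MLR-positive at 0 h). KIT rose by 4.94 and GPX4 fell by 1.27 against 6 h alone, as the mean of both classes; a value of 4 is the floor.

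Of 14 measured T cell markers 7 rose with CD4 T cells, 10 adjusted over the list alone, among them TRBC1, a T cell receptor constant chain (1.87 ± 0.25, adjusted p = 0.0022), the transcription factors LEF1 (2.79 ± 0.42, 0.0043) and BCL11B (1.64 ± 0.30, 0.013) and the receptor chain CD247 (2.96 ± 0.48, 0.0064), each in 8 of 8 donors. Camera called the list (adjusted p = 2e-08), and the call held with an estimated correlation (adjusted p = 0.0039), as it did within each class (0.031 and 0.0043). These are the only 3 list calls of any comparison that held so. Mean log2 levels of the list were 6.49 ± 0.04 (SD, n = 4) and 6.53 ± 0.09 (n = 3) at 0 h in MLR-negative and MLR-positive donors, 7.21 ± 0.32 and 6.78 ± 0.36 at 6 h alone, and 8.19 ± 0.31 and 8.15 ± 0.24 with CD4 T cells (n = 4 each), although the samples had been depleted with CD3 beads. CD3D rose by 1.29 ± 0.28 (7 of 8 donors, adjusted p = 0.029), a call that ended in 11 of 22 alternatives. IL7R, the interleukin 7 receptor (2.92 ± 0.30), CD69 (2.36 ± 0.34) and the lectin KLRB1 (2.77 ± 0.43), which other lists hold and T cells also express, rose in 8 of 8 donors, with adjusted p of 0.00035, 0.0037 and 0.0049. Other probe sets of LEF1 (-0.96 ± 0.40), BCL11B (-0.62 ± 0.50) and CD247 (-0.78 ± 0.63) gave the opposite sign, while 1 each of LEF1 (0.59 ± 0.36) and BCL11B (3.76 ± 0.50) kept it. The BCL11B call ended in 2 of 22 alternatives.

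Of 28 genes of oxidative phosphorylation 2 fell with CD4 T cells, NDUFA2 (-0.94 ± 0.14) and COX7A2 (-0.48 ± 0.12; adjusted p of 0.0043 and 0.044, 8 of 8 donors each), and 7 fell and 1 rose adjusted over the list alone. Camera called the list lower (adjusted p = 0.0096), with adjusted p = 0.44 with an estimated correlation and 0.063 without MLR-positive donor 2. The COX7A2 call ended in 16 of 23 alternatives and that on NDUFA2 in 1. Other probe sets of NDUFA2 gave 0.26 ± 0.33 and 0.56 ± 0.46. Of 11 platelet markers, 2 rose and 4 did adjusted over the list alone, TUBB1 by 1.78 ± 0.38 (7 of 8 donors, adjusted p = 0.028) and the chemokine PF4 by 2.29 ± 0.57 (8 of 8, 0.049), calls that ended in 9 of 22 and 15 of 23 alternatives, and camera gave adjusted p = 0.08. Among monocyte genes, S100A12 fell by 0.86 ± 0.16 (8 of 8, 0.015), LST1 fell by 0.63 ± 0.12 (8 of 8, 0.013) and the kinase IRAK1 fell by 1.12 ± 0.17 (8 of 8, 0.0047), while IL23A, an inflammatory cytokine subunit, rose by 1.50 ± 0.27 (8 of 8, 0.012). The calls on S100A12, LST1 and IL23A ended in 5, 4 and 1 alternatives. Other IL23A probe sets gave 0.86 ± 0.55, 0.43 ± 0.44 and -0.19 ± 0.75. CD14 was at -0.65 ± 0.19 (8 of 8 donors, adjusted p = 0.093). limma found 0 of 39 interferon-stimulated genes changed over all genes and 0 adjusted over the list alone (median -0.22, camera adjusted p = 0.15), and the unadjusted count over all genes was 2249. In the panel, CXCL10 was at 1.18 ± 0.44 (5 of 8 donors, adjusted p = 0.17) and the chemokine receptor CCR7 at 1.13 ± 0.55 (7 of 8, 0.30), neither past the threshold.

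Camera called none of the remaining lists with CD4 T cells. Of 27 genes of mature migratory dendritic cells 2 rose, IL7R and the cystatin CST7 (1.29 ± 0.31, 7 of 8 donors, adjusted p = 0.046), and 3 adjusted over the list alone (median -0.03, mean 0.20; camera adjusted p = 0.71). The call on CST7 ended in 16 of 23 alternatives. Of 26 genes induced by interferon gamma 1 fell, also 1 adjusted over the list alone, VAMP5 (-1.04 ± 0.20; median -0.02, mean 0.08; camera adjusted p = 1). CD69 was the 1 gene of 10 activated T cell cytokines and receptors that rose (2 adjusted over the list alone; median -0.09, mean 0.17; 0.61), and KLRB1 the 1 of 8 NK and cytotoxic markers (2 adjusted over the list alone; 0.35). IL23A was the 1 of 31 inflammatory cytokines and NF-kB targets (1 adjusted over the list alone; 0.71). 1 gene fell in each of the lists of 22 classical monocyte genes (S100A12; 1 adjusted over the list alone; 0.18), 17 CD16 monocyte genes (LST1; 1; 0.13), 21 macrophage and scavenger genes (the lipid carrier APOE, -0.85 ± 0.19; 2; 0.09) and 20 toll-like receptor and inflammasome genes (IRAK1; 4; 0.08). The same was so of 19 stress and immediate early genes (JUNB, -0.80 ± 0.17; 1; median 0.03, mean 0.05; 0.88) and 21 apoptosis regulators (BCL2, -0.84 ± 0.18; 4; 0.61). In limma 0 genes changed among 15 of MHC class II presentation (camera adjusted p = 0.92), 22 costimulatory and inhibitory ligands (0.22), 9 B cell markers (0.82), 14 granulocyte markers (0.92), 6 red cell markers (0.35), 9 plasma cell and proliferation genes (0.76), 15 cholesterol synthesis genes (0.90; median -0.01, mean 0.04) and 23 genes of glycolysis and hypoxia (0.48), and 0 adjusted over each list alone. Of 9 plasmacytoid dendritic cell markers (0.44), 17 genes induced by glucocorticoids (0.84) and 27 ribosomal proteins (0.71) 0 changed over all genes; adjusted over the list alone 1 rose, 1 rose and 1 fell, and 1 rose. The calls on APOE, BCL2, JUNB and VAMP5 ended in 11, 10, 9 and 6 of 23 alternatives. Other probe sets of APOE (0.02 ± 0.64) and BCL2 (0.50 ± 0.48 and 0.34 ± 0.29) gave the opposite sign, while 1 each (-1.56 ± 0.52 and -0.97 ± 0.56) kept it. Of 25 other probe sets of 12 list members past the threshold 9 gave the opposite sign. With fry, platelet markers had adjusted p = 0.046. Camera also called interferon-stimulated genes lower without MLR-negative donor 1 (0.018) or 2 (0.017), and platelet markers higher without MLR-negative donor 2 (0.016) or 3 (0.041). It called toll-like receptor and inflammasome genes lower without MLR-negative donor 3 (0.041) or MLR-positive donor 1 (0.033), and macrophage and scavenger genes lower without MLR-negative donor 3 (0.022).

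The count of 306 depended on the samples. It was 105, 161, 198 and 90 without MLR-negative donors 1, 2, 3 and 4, and 198, 120, 132 and 148 without MLR-positive donors 1, 2, 3 and 4. It was 145 without the MLR-negative CD4 sample of donor 1 and 110 without that sample and the MLR-positive 6 h sample of donor 4. Without the donor block it was 410, with the samples of the contrast alone and the block 73, and with a trend and robust variances 504. With the GAPDH ratio as a covariate it was 219, with 151 of the 306 genes still called. Of the 38 calls in MLR-positive donors 13 remained. In those donors the ratio was 2.12 at 6 h alone and 1.46 with CD4 T cells, and in MLR-negative donors 1.99 and 1.82. The log2 ratio of 3' to 5' ACTB signal differed more in MLR-negative donors (4.59 and 3.94) than in MLR-positive donors (3.94 and 3.75). The 2 ratios thus disagreed on the class with the larger shift.

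Within classes, CD4 T cells went with 61 changed genes in MLR-negative donors (43 higher, 18 lower) and 38 in MLR-positive donors (31 higher, 7 lower). KIT rose by 5.46 ± 0.56 and 4.43 ± 0.56, MYB by 4.49 ± 0.43 and 4.57 ± 0.43 and GATA3 by 3.58 ± 0.34 and 3.74 ± 0.34, with adjusted p of at most 0.0063. In MLR-positive donors camera also called interferon-stimulated genes lower (median -0.55, 0.0022), and inflammatory cytokines (0.52, 0.0098), glycolysis and hypoxia (0.35, 0.027) and oxidative phosphorylation (-0.23, 0.004) away from 0. With an estimated correlation their adjusted p was 0.60, 0.51, 0.18 and 0.44. For oxidative phosphorylation the median in MLR-negative donors was -0.18 and the test of the difference between classes gave adjusted p = 0.42. 13 genes were shared, and 13 moved the same way. Independent calls would share 0.188, a level that is too low because both classes were tested with the same estimate of spread per gene. limma found 0 genes whose response to CD4 T cells differed between classes, with 759 at an unadjusted p under 0.05 against 616 by chance, and the smallest p was that of DPY19L3-DT (2.17 ± 0.38, adjusted p = 0.41). Inflammatory cytokines and NF-kB targets had a difference in response, MLR-positive minus MLR-negative, with a median of 0.90 over 31 genes, 29 of them positive, among them PTGS2, the prostaglandin synthase (0.93 ± 0.37, adjusted p = 0.76), and CXCL3 (1.21 ± 0.55, 0.78). Camera gave adjusted p = 6e-05, and adjusted p = 0.50 with an estimated correlation, and without both samples that stood apart the camera value was 0.20. Interferon-stimulated genes had a median difference of -0.54 (camera adjusted p = 0.0025, and adjusted p = 0.67 with an estimated correlation), which was not past the threshold without the MLR-positive 6 h sample of donor 4 (0.35), without that donor (0.32), or without MLR-negative donor 1 or 2 (0.19 and 0.15). Genes of glycolysis and hypoxia had a median of 0.29 (0.0091, and adjusted p = 0.14 with an estimated correlation), with 0.11 without both samples that stood apart.

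The within-class counts also moved with the samples. With the samples of the contrast alone they were 0 and 1, against 1577 and 1599 at an unadjusted p under 0.05 with all samples. The MLR-negative count was 10, 23 and 9 without MLR-negative donors 1, 2 and 4, 34 without MLR-positive donor 2, 22 without the MLR-negative CD4 sample of donor 1 and 6 without both samples that stood apart. The MLR-positive count was 9, 2, 13 and 17 without MLR-positive donors 1, 2, 3 and 4, 23, 15 and 3 without MLR-negative donors 1, 2 and 4, 21 without the MLR-negative CD4 sample of donor 1 and 24 without both. Without the donor block the MLR-positive count was 85.

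Between MLR-positive and MLR-negative donors, the contrast that bears on the purpose the labels give, no gene passed the threshold in any condition. With CD4 T cells, the interferon-induced chemokines CXCL10 and CXCL9 were 1.55 ± 0.33 and 0.91 ± 0.24 higher on the log2 scale in MLR-positive donors (SE; 4 against 4; adjusted p = 0.38 and 0.46), the cytokine IL1B was 1.59 ± 0.58 higher (0.53), the inhibitory ligand CD274 1.14 ± 0.38 (0.50) and the dendritic cell maturation marker LAMP3 1.02 ± 0.44 (0.57). None of these passed. At 6 h alone CXCL10 was at 0.08 ± 0.43, CXCL9 at -0.63 ± 0.29 and IL1B at 0.13 ± 0.85, and at 0 h at 0.91 ± 0.83, 0.11 ± 0.43 and 0.26 ± 0.39. The costimulatory ligand CD86 was at 0.81 ± 0.41 with CD4 T cells and IL15 at -0.78 ± 0.43 (adjusted p = 0.60 and 0.61). The interferon-stimulated genes IFIT1 and MX1 were at -0.05 ± 0.97 and -0.38 ± 0.68 with CD4 T cells, at 1.26 ± 1.2 and 1.22 ± 0.81 at 6 h alone and at 1.18 ± 1.5 and 0.73 ± 1.3 at 0 h.

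**Figure D5:**
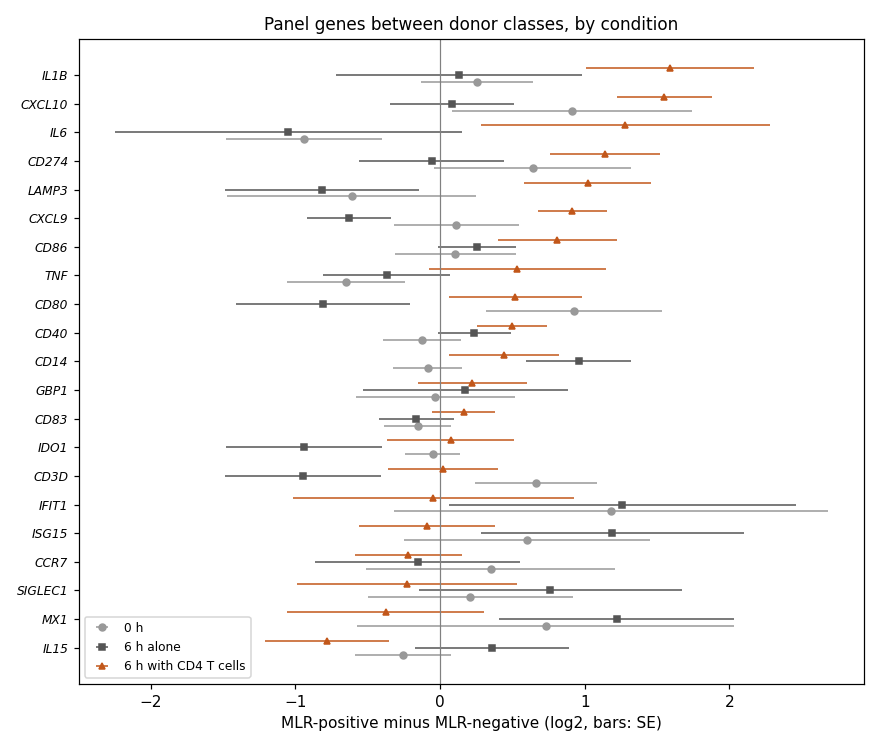
Difference in log2 intensity, MLR-positive minus MLR-negative (x axis), of the measured panel genes (y axis) at 0 h (3 against 4 donors), at 6 h alone and at 6 h with CD4 T cells (4 against 4 each), with points for the limma estimate and bars for its SE. CXCL10 lies at 1.55 and IL1B at 1.59 with CD4 T cells, and at 0.08 and 0.13 at 6 h alone; no gene passed the threshold.

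With CD4 T cells, limma found 0 genes past the threshold between classes, with 1078 at an unadjusted p under 0.05 against 616 by chance, and 5.63% of genes had groups that did not overlap, against 2.86% by chance. The smallest p-values were those of CEP83-DT (2.03 ± 0.24) and SLC35F6 (2.34 ± 0.30), both with adjusted p = 0.15, GLI1, a transcription factor of the hedgehog pathway (1.92 ± 0.26, 0.20), and the T cell and monocyte coreceptor CD4 (1.49 ± 0.22, 0.26). Another probe set of SLC35F6 gave -0.07 ± 0.25, and a dim one of CD4 gave 0.19 ± 0.12. Of 31 inflammatory cytokines and NF-kB targets 30 were higher in MLR-positive donors (median 0.63; camera adjusted p = 1.6e-06, and adjusted p = 0.36 with an estimated correlation), among them CXCL5 (1.23 ± 0.36) and CXCL3 (1.34 ± 0.44), each with adjusted p = 0.50. The MLR-negative CD4 sample of donor 1, which stood apart, was short of culture rises by 0.996. Without it 30 of the 31 were still higher, with a median of 0.38 (camera adjusted p = 1e-04). The GAPDH ratio also differed, at 1.82 in MLR-negative and 1.46 in MLR-positive donors. Of 27 ribosomal proteins 26 were lower (median -0.30; camera 3.8e-06), such as RPL10A (-0.86 ± 0.24, adjusted p = 0.50). Platelet markers (median -1.0; 0.014), with TUBB1 at -2.09 ± 0.56 (adjusted p = 0.48), and genes induced by glucocorticoids (median -0.43; 0.049), with the receptor chaperone FKBP5 at -1.64 ± 0.38 (0.39), were lower as well. Without the sample that stood apart they had adjusted p of 0.05, rounded and still under the threshold, and 0.049, and ribosomal proteins 2.3e-06. The glucocorticoid call ended without any of 5 donors (MLR-negative 2 and 3, MLR-positive 2, 3 and 4; 0.058 to 0.13). All of these lists had adjusted p = 0.36 with an estimated correlation. Adjusted over the list alone, 0 genes changed in the inflammatory and ribosomal lists, 1 in the platelet list and 4 in the glucocorticoid list. The exact permutation test of list levels gave p = 0.029, the smallest that 4 against 4 allows, for ribosomal proteins (13.67 ± 0.10 in MLR-positive and 13.98 ± 0.11 in MLR-negative donors, SD) and for glycolysis and hypoxia (11.52 ± 0.05 and 11.27 ± 0.13), both 0.48 after adjustment over the lists and conditions. For inflammatory cytokines and NF-kB targets the exact permutation test gave p = 0.11, also 0.48 after that adjustment. Their levels overlapped, at 11.19 to 12.04 in MLR-positive and 10.17 to 11.47 in MLR-negative donors. For platelet markers and genes induced by glucocorticoids the exact permutation test gave p = 0.057 each, 0.48 after adjustment. With fry 0 of 26 lists were called. The count of genes between classes was 5 with no filter on dim probe sets and 1 with every probe set on its own.

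At 6 h alone limma found 0 genes between classes, with 517 at an unadjusted p under 0.05 against 616 by chance and 2.67% of genes without overlap against 2.86%. The smallest p was that of CLPB, a mitochondrial disaggregase (2.31 ± 0.30, adjusted p = 0.38), then S100P (2.63 ± 0.43, 0.99). Another CLPB probe set had the opposite sign (-1.17 ± 0.65). Of 39 interferon-stimulated genes 37 were higher in MLR-positive donors (median 0.54; camera adjusted p = 2.6e-06, and adjusted p = 0.74 with an estimated correlation). This call ended without the MLR-positive 6 h sample of donor 4 (0.19) and without MLR-negative donor 2 (0.21). Granulocyte markers had a median of 0.36 over 14 genes (camera 0.01, and adjusted p = 0.74 with an estimated correlation), with CAMP, an antimicrobial peptide, at 1.77 ± 0.65 (adjusted p = 0.99). Neither list had a gene past the threshold over all genes or adjusted over the list alone, and without MLR-positive donor 3 the count over all genes was 1.

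At 0 h limma also found 0 genes between classes, with 567 at an unadjusted p under 0.05 against 616 by chance and 5.80% of genes without overlap against 5.71%. LINC01718 (2.17 ± 0.30) and the ciliary protein TCTN2 (-1.90 ± 0.27) had the smallest p-values, both with adjusted p = 0.52. Another TCTN2 probe set kept the sign (-1.35 ± 0.82). Camera called 0 of 26 lists, and fry also 0. Median differences of the markers of other cell types were 0.36 for red cells, 0.30 for granulocytes, 0.19 for T cells, 0.15 for platelets, 0.12 for B cells and 0.0008 for NK cells. Interferon-stimulated genes were called with 1 donor left out: higher in MLR-positive donors without MLR-negative donor 1 (0.00046) or 4 (0.017), and higher in MLR-negative donors without MLR-negative donor 3 (0.00038). The count of genes was 2 with no filter and 2 with all samples and the donor as a random effect.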

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

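The tests of progenitor, mast cell and innate lymphoid markers and those on the samples that stood apart were chosen only after the results were seen, as was the way they and RNA quality at 0 h were read, while those of leftover T cells, of cell makeup and RNA quality at 0 h and of other splits were set beforehand.

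The genes higher with CD4 T cells include members of the T cell marker list. Outside that list they include KIT, MYB, GATA3, GATA2 (2.64 ± 0.51), TAL1 (2.84 ± 0.40) and SOX4 (2.69 ± 0.32). T cells also express genes outside the list, such as IL7R, so lying outside it does not set a gene apart from T cells. RNA of leftover CD4 T cells could be 1 source, since the T cell marker list rose by a median of 1.11. CD3 beads had been used to remove such cells, however. In culture with no T cells added the list's median was 0.70 in MLR-negative and 0.11 in MLR-positive donors. Camera called the former (adjusted p = 0.022, and 0.27 with an estimated correlation) but neither the latter (0.66) nor the difference between classes (0.19). RNA of cells with mast cell and basophil markers could be another source: 6 members not named elsewhere had a median of 1.03, all 6 of them positive. Of these 1 was past the threshold (HPGD, 1.36 ± 0.29), while HPGDS (1.98 ± 0.34) and TAC3 (1.96 ± 0.40), both seen before the test, also rose. Without the filter on dim probe sets the median was 0.949 over 10 members not named elsewhere, 8 of them positive. Markers of CD34 progenitors had a median of 0.392 over 8 genes, between the bounds of 0.25 and 0.5, which left that source open. Without the filter it was 0.995 over 16 genes, 15 of them positive, and with members already named 1.08. Those of megakaryocyte and erythroid progenitors (-0.306 over 5) and of innate lymphoid cells (0.0178 over 7) lay under 0.25. Without the filter their medians were 0.096 over 10 and 0.371 over 13. These 2 lists excluded nothing, since their few members went both ways and members already named were left out (medians with them 1.78 and 0.561). Induction in monocytes by contact with T cells was not tested and stays open.

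The MLR-positive 6 h sample of donor 4 and the MLR-negative CD4 sample of donor 1 lay towards the 0 h samples. A mixture with RNA of uncultured cells, taken as the mean of all 0 h samples, was tested over 286 genes that rose and 174 that fell in culture. In the MLR-positive sample the falls it lacked implied 40.1% of such RNA. The shortfall of its rises was 0.772, against 0.595 predicted, a gap of 0.177, so a mixture may account for part of its shift. However, its interferon-stimulated genes lay at 11, against 10.41 at 0 h in the same donor, and genes induced by glucocorticoids at 12.2 against 11.33. The other MLR-positive samples at 6 h alone lay at 9.29 to 9.45 and 10.63 to 11.2. A mixture would be expected to lie between such levels, so it does not account for these lists. In the MLR-negative sample the implied share was 30.3% and the shortfall 0.996 against 0.421, a gap of 0.575; it passed the bound of 0.5 by less than the spread of the other 7 samples (-0.19 to 0.22), which leaves the mixture open. Among the 8 samples of its condition the MLR-positive sample had the highest GAPDH ratio and ranked 3 for ACTB, and the MLR-negative sample ranked 2 and 4, which leaves RNA quality open for both. The same donors' other cultured samples, at 38.2 and 27.99 on the first component, lay within the ranges of the other 6 samples of their conditions (18.64 to 40.91 and 25.01 to 42.57), which argues against a slower response of the donor's cells in any culture; a slower response in that 1 culture stays open.

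Between classes at 0 h no gene passed the threshold, so differences in cell makeup or RNA quality bear only on values short of it. The largest median difference of 6 marker lists was 0.355 (red cells), between the bounds of 0.25 and 0.5 set beforehand, which leaves a different makeup open. The class ranges of 2 of 2 control ratios overlapped, the sign set beforehand against RNA quality, but with 4 and 3 samples that bound was too weak: the ratios were higher in MLR-positive donors by 1.1 (GAPDH) and 0.83 (ACTB) pooled SD. RNA quality therefore stays open. Donor class itself stays open as an explanation of those values.

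A value far from the other 3 of its group was found in 71 of 960 groups of 4 values, against 48 by chance, since chance sets such a value apart in about 1 of 20 groups. That rate holds for independent values from a normal distribution. The values here came from the same samples and some were equal at the floor, so 48 is only a rough guide. The numbers that follow are the gap to the nearest other value over the group's range. The MLR-positive 6 h sample of donor 4 held 9 of them, the MLR-negative CD4 sample of donor 1 held 6, and the MLR-negative 0 h sample of donor 3, which did not stand apart on the first component, also held 9.

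At 0 h in MLR-negative donors 1 value stood apart for CD247 (0.877), CX3CR1 (0.856), EIF2AK2 (0.836), GATA2 (0.867), GLI1 (0.959), HDC (0.955), KCNJ15 (0.907), KIT (0.953), LGMN (0.869), MET (1), MTARC1 (0.832), MX1 (0.835), NDUFB5 (0.938), NRP1 (1), PF4 (0.935) and RORA (0.834). The same held there for the lists of activated T cell cytokines and receptors (0.838), platelet markers (0.952) and stress and immediate early genes (0.897), and for the GAPDH ratio (0.867). At 6 h alone in MLR-negative donors it held for COL22A1 (0.854), CT75 (0.867), CXCL10 (0.86), CXCL5 (0.982), GOLM1 (0.952), PSMB8 (0.913), PSMB9 (0.846), RPL10A (0.853), TRIM65 (0.889), TUBB1 (0.875), ZFP36 (0.858) and the first principal component (0.906).

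With CD4 T cells in MLR-negative donors 1 value stood apart for BST2 (0.882), CD3D (0.881), CXCL10 (0.884), GATA3 (0.95), GCLM (0.839), HDC (0.842), IL23A (0.905), IL7R (0.933), IRAK1 (0.858), LINC01718 (0.86), MCL1 (0.88), NQO1 (0.835), PDE4DIP (0.852) and PRX (0.866). It did too for plasma cell and proliferation genes (0.873), stress and immediate early genes (0.857) and apoptosis and cell death regulators (0.86). At 6 h alone in MLR-positive donors it did for ABCC4 (1), CHRM3 (0.856), CT75 (0.842), CTSB (0.842), CXCL2 (0.885), CXCL5 (0.993), IRAK2 (0.863), NR4A2 (0.883), TLR8 (0.999), TRAF1 (0.969) and TXN (0.889), and for interferon-stimulated genes (0.907), inflammatory cytokines and NF-kB targets (0.88) and NK and cytotoxic cell markers (0.905). With CD4 T cells in MLR-positive donors it did for ADM (0.909), CXCL9 (0.905), EVA1B (0.907), IRAK1 (0.854), NR4A2 (0.899), PRX (0.835), T cell markers (0.923) and the ACTB ratio (0.871).

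Camera found 6 lists whose response differed between classes, and none with an estimated correlation or, but for glycolysis and hypoxia (0.018), with fry. For CD4 T cells these were interferon-stimulated genes (adjusted p = 0.0025, median -0.54), inflammatory cytokines and NF-kB targets (6e-05, 0.90) and glycolysis and hypoxia (0.0091, 0.29). For culture they were classical monocyte genes (0.044, 0.26), stress and immediate early genes (0.0069, -0.35) and toll-like receptor and inflammasome genes (0.0065, 0.35).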

How the results depend on the processing

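Leaving out the samples that stood apart and the GAPDH covariate were alternatives chosen only after the data were seen. Of the values of named genes 30447 kept their direction and side of the threshold, 357 changed direction while short of it in both settings (CD80, IL1B, IFIT1 and CD40 with CD4 T cells among them), 382 were past it only in the alternative and 872 only as reported. Among these values of named genes 0 past it in either setting changed direction. Over all genes some did. With no filter on dim probe sets 9 of the 306 genes called with CD4 T cells had the opposite sign and 172 were still called. In culture 43 of 3536 had the opposite sign and 2879 were still called. With the 60th percentile filter the opposite sign came from 2 and 16 genes. Of the list tests 4078 kept their side of the threshold, 109 were past it only in the alternative, 99 only as reported, and 4 were called in the other direction. The cause was not tested.

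The count of 306 genes with CD4 T cells was 73 with the samples of the contrast only (65 of the 306 still called), 504 with a trend and robust variances, 145 without the MLR-negative CD4 sample of donor 1 (136 still called) and 110 without both samples (97 still called). Leaving out a donor gave 90 to 198. The MLR-negative count of 61 was 0 with the samples of the contrast only, 35 with deposited scaling, 35 with scaling to the 75th percentile, 34 with the 60th percentile filter, 22 without the MLR-negative CD4 sample of donor 1 and 6 without both, and 9 to 53 without a donor. The MLR-positive count of 38 was 85 without the donor block, 95 with the block as a random effect, 1 with the samples of the contrast only, 96 with the 60th percentile filter, 68 with array A only, 145 with a trend and robust variances, 63 with array weights, 21 without the MLR-negative CD4 sample of donor 1 and 24 without both, and 2 to 32 without a donor. No alternative tried gave a gene whose response to CD4 T cells differed between classes.

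With every probe set the culture counts of 3536, 1961 and 1776 were 6705, 3506 and 3075, over more tests. With the samples of the contrast only the class counts were 950 and 59. Leaving out a donor gave 2655 to 3316, 1002 to 1978 and 627 to 1823, and for genes whose culture response differs 0 to 1.

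Between classes, the count at 0 h was 2 with all samples and a random block and 2 with no filter, and 0 with each donor left out. The count with CD4 T cells was 5 with no filter and 1 with every probe set, and at 6 h alone it was 0 to 1 without a donor. Gene list calls fell from 40 to 3 with an estimated correlation, and were 37 to 54 without a donor.

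The list of interferon-stimulated genes changed direction between classes in 4 alternatives. With CD4 T cells it was higher in MLR-positive donors without MLR-negative donor 1 (0.05), without that donor's CD4 sample (0.05) and without both samples (0.05), with a range over the donors left out of 0.014 to 0.98. At 0 h it was lower without MLR-negative donor 3 (0.00038), with a range of 0.00038 to 0.74. The MLR-positive donor without a 0 h sample gives no value at 0 h.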

Other observations

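The tests of NRF2 and ATF4 targets were chosen only after the culture result was seen, and members already seen were left out of them; the other splits were set beforehand.

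Culture raised the thioredoxin reductase TXNRD1 by 3.38 ± 0.19 on the log2 scale, the quinone reductase NQO1 by 4.19 ± 0.32 and the aldo-keto reductase AKR1C1 by 5.57 ± 0.40 (adjusted p of at most 7.2e-07). The glutathione synthesis enzyme GCLC rose by 2.90 ± 0.28, the autophagy receptor SQSTM1 by 2.39 ± 0.21, the glutathione reductase GSR by 1.89 ± 0.25, thioredoxin TXN by 1.88 ± 0.19 and the sulfiredoxin SRXN1 by 1.83 ± 0.21. The biliverdin reductase BLVRB fell by 1.04 ± 0.14, the carbonyl reductase CBR1 fell by 2.25 ± 0.48 and the transketolase TKT fell by 0.60 ± 0.16. The asparagine synthetase ASNS rose by 2.50 ± 0.47, while the serine synthesis enzyme PSAT1 was at -0.03 ± 0.24 (adjusted p = 0.94).

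Higher activity of NRF2, a transcription factor of the oxidative stress response, may account for part of the culture rises. Of 25 measured NRF2 targets not seen before 18 rose and 2 fell, with a median of 1.12 (camera p = 4.6e-09, and 0.0056 with an estimated correlation). For ATF4, a transcription factor of the amino acid response, the median of 27 targets was 0.331, with 11 higher and 3 lower (0.0043 and 0.037), which leaves its part open. Other regulators were not tested.

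Other splits of the same samples were counted for each comparison. The CD4 T cell count of 306 was as large in 1 of 100 splits, the real one, with 10 in the highest other. The culture count of 3536 was as large in 1 of 64, with 1463 in the highest other, a split that exchanged the conditions of 1 donor only. Both shares are the smallest these splits allow, so chance is unlikely for these counts but not excluded. The counts within classes, 61 and 38 with CD4 T cells and 1961 and 1776 in culture, came from 8, 8, 8 and 4 splits, too few for a share under 0.05, and the highest others were 0, 2, 4 and 1. For the counts of 0 that compare classes the splits decide nothing, since any of the 35 splits gives as many as 0 by construction. The highest others were 2 for the response to CD4 T cells, 1 for culture, 1 at 0 h, 2 at 6 h alone and 3 with CD4 T cells.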
